A study of Caenorhabditis elegans with 4 samples.

How the data were processed

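Anti-GFP ChIP-seq and input libraries were made from L1 larvae of strain OP305 fixed with 2% formaldehyde, per the labels' protocols. The 4 samples fell into 2 groups by their titles, NHR-11 ChIP and input, with replicates 1 and 2 in each. Peak lists were held for both ChIP replicates and for the series as a whole, and the input libraries had no file of their own here. Peaks were called with PeakSeq on build WS220, per the file headers and the source column. The aligner and the version of PeakSeq are not given in the sources used here. Neither is how the input entered the calling, nor whether the reads of both replicates were pooled for the series list.

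Each peak's score is a q-value given by the authors in the deposited lists, below 0.001 for every peak. It was read as a q-value because the score times the peak's rank never fell with rank in any list. That is how a p-value multiplied by the number of tests and divided by its rank behaves. Peak height was computed here as −log10 of the q-value deposited by the authors. It was used to rank, describe and compare peaks within a list. Heights of overlapping peaks were also compared between lists, in the correlation of replicates and in the ratio of series to summed replicate heights, each with a permutation test across peaks. A q-value depends on sequencing depth and peak width as well as on enrichment, so heights are not occupancies. The series list lacked 12 rank numbers, replicate 1 lacked 3 and replicate 2 lacked 1; those peaks were not analysed here. Read counts were not given, so no depth or depth-based precision can be stated.

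Overlap was counted at 1 bp or more. Where a peak overlapped several peaks of another list, that with the lowest q was used for paired values. Overlap between replicates and central position were tested with circular shifts, in which all peaks of a chromosome move by a common random offset and wrap round (10000 shifts, two-sided, smallest p 0.0001). Differences of medians or means and correlations used 100000 permutations (two-sided, smallest p 1e-05). Chromosome shares used two-sided exact binomial tests, tables of counts used Fisher's exact test, and shares carry exact Clopper-Pearson 95% intervals. These tests treat peaks as independent, which neighbouring peaks are not, so counts in windows of 500 kb were also compared. Chromosome length was taken as the last peak end in any of the 3 lists, because the headers give no lengths. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

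Methods were tested on simulated data. For the replicate overlap, with lists of 1247 peaks, 700 planted shared peaks gave 705 counted as shared, and 7 of 200 random lists had p under 0.05. For the share on X, counts out of 3006 peaks were drawn from the binomial model that the test itself assumes. With 1.5 times the share on X, 200 of 200 draws were called, and 7 of 200 unchanged draws were. These draws treat peaks as independent, so they do not give the rate of false calls for peaks that lie close together.

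Before the data were examined, the comparisons of replicates, of X with autosomes and of chromosome centres with arms were fixed, with their alternatives. The rule for named peaks was fixed then too: without an annotation of the lists' build it names the 20 highest series peaks found in both replicates, by position only. No genome or annotation of WS220 was used here. A gene table of assembly WBcel235 served only for names and for the number of genes per chromosome. For this reason 4 planned analyses were not run: peaks near gene 5′ ends, 31 fixed gene lists, 7 fixed sequence words, and the loci of the genes on the transgene. Tests of chromosomes other than X, of the highest peaks, of X in the comparison of centres, of wide peaks and of chromosome IV across lists were chosen after the data were seen. Alternatives covered the overlap rule, a stricter threshold, peaks found in both replicates, each replicate list alone, the definition of the centre and the null model.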

Results

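Binding of NHR-11, a transcription factor of the nuclear hormone receptor family, was mapped in Caenorhabditis elegans L1 larvae by chromatin immunoprecipitation and sequencing (ChIP-seq). The larvae were hermaphrodites of strain OP305, made by microparticle bombardment. This strain carries a transgene that expresses NHR-11 fused to TY1, EGFP and FLAG tags, together with unc-119, a gene whose function rescues movement in the unc-119 mutant background and so marks transformed animals. Chromatin bound by the fusion protein was collected with antibodies against GFP, and part of each lysate was kept as input. The 4 samples comprised 2 ChIP libraries and 2 input libraries. Stage labels read L1 26dC, while the design text gives a culture temperature of 20 °C. Peak lists were analysed for ChIP replicate 1, ChIP replicate 2 and the whole series. Input libraries had no values of their own here, and read numbers were not known, so the depth behind each peak is unknown. Peak height is given as −log10 q, where q is the authors' value for that peak. All positions are on build WS220.

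The series list held 3006 peaks, which covered 1447110 bp, or 1.45% of the length analysed. Median peak width was 392 bp (interquartile range 274 to 574 bp) and median −log10 q was 5.37. The replicate 1 list held 1247 peaks with a median width of 397 bp and a median −log10 q of 5.10. The replicate 2 list held 1190 peaks with a median width of 394 bp and a median −log10 q of 5.14.

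The strongest NHR-11 peaks lay mostly on the X chromosome. Of the 20 highest series peaks found in both replicates, 14 were on X, 2 on II, 2 on III, 1 on IV and 1 on V, and none was on I. The highest lay at X 14525244 to 14526427 (1184 bp), with q = 2.255e-195 in the series list and a −log10 q of 115 ± 16.2 in the replicate lists (mean ± SD, n = 2). The next was at X 8035562 to 8036985, with −log10 q of 151 in the series list and 92.8 ± 5.21 in the replicates (SD, n = 2). The peak at X 2996139 to 2997785 reached 148 in the series list and 88.3 ± 0.456 in the replicates (SD, n = 2). The highest autosomal peak of the series list, at III 4281790 to 4283509, had −log10 q of 140 there and 72.3 ± 0.817 in the replicates (SD, n = 2). In both replicate lists the highest peak of all was on I and had no series counterpart, as described below. A second strong peak on III lay at 4237494 to 4238148 and had a replicate mean of 51.6 ± 0.804 (SD, n = 2).

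Among the other 15 of these peaks, the remaining 11 on X began at 4208342, 11093679, 16929137, 9465354, 6296128, 12362595, 13700152, 16056057, 6740646, 11937026 and 1503352. The peak on IV spanned 14032795 to 14034538, the peak on V 1151047 to 1152116, and the peaks on II 5543323 to 5544390 and 10547675 to 10553078. The 20 peaks were 655 to 5404 bp wide, and their series −log10 q ran from 85.7 to 195. Each ranked 74 or better in the replicate 1 list and 72 or better in the replicate 2 list. At X 6740646 to 6744380, the single series peak overlapped 3 peaks in each replicate list, and the widest of the 20, on II, overlapped 3 and 2.

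**Figure D1:**
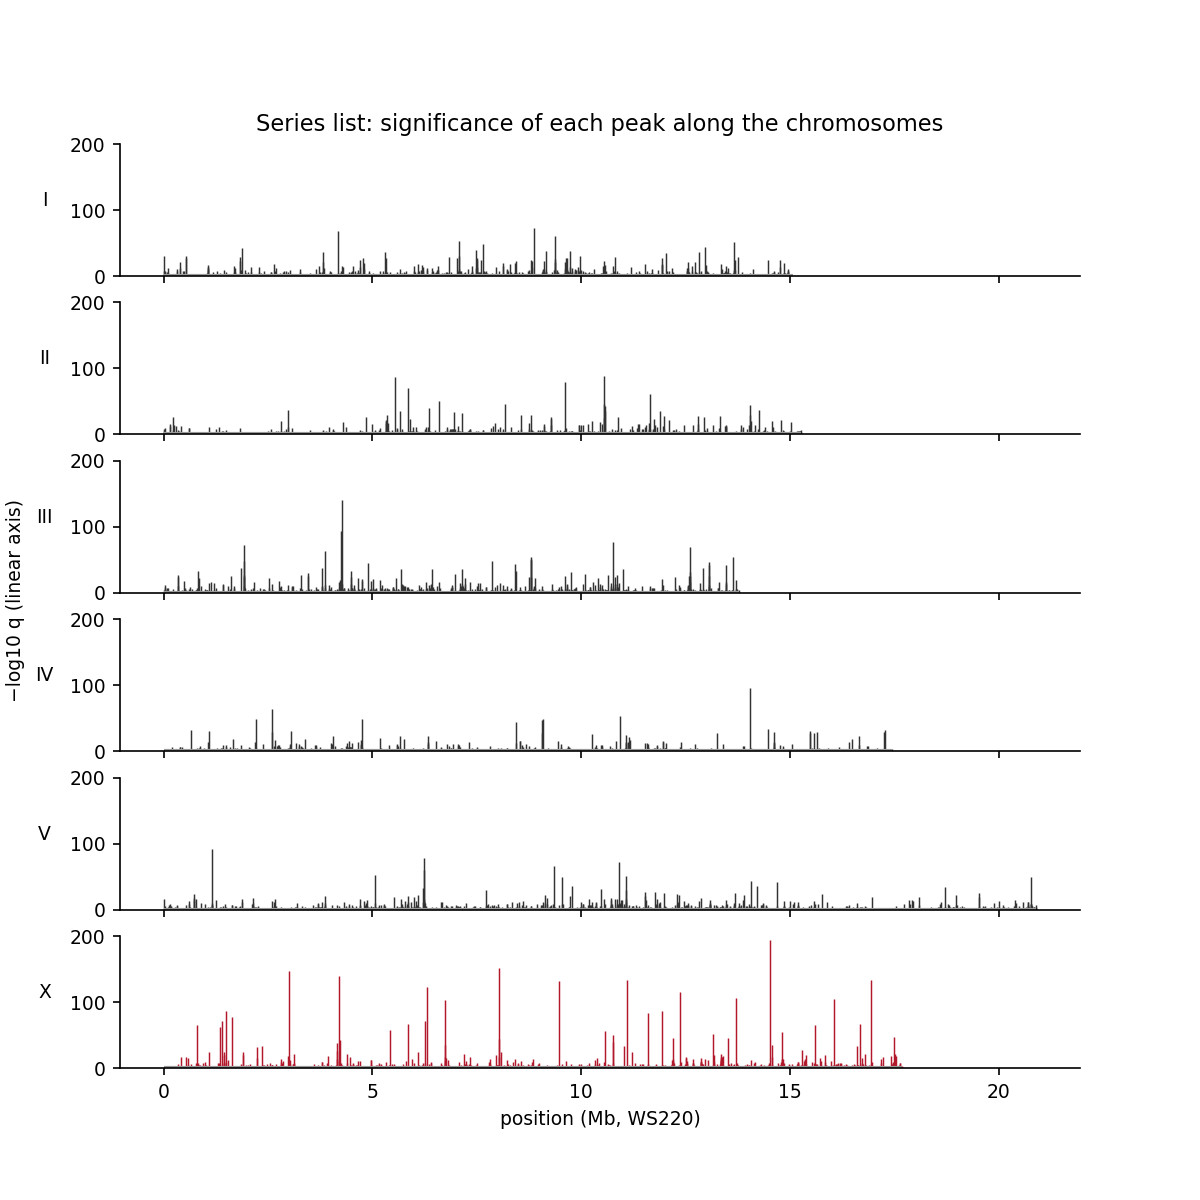
Series peaks along the 6 chromosomes, with position in Mb (WS220) on the x axis and −log10 q on a linear y axis. Each line is 1 peak, X is drawn in red, and its highest line reaches 195 against 140 for the highest autosomal peak, on III.

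Replicate lists were compared to ask how far the binding map repeated between the ChIP libraries. Of the 1247 replicate 1 peaks, 871 (69.8%, exact 95% interval 67.2 to 72.4%) overlapped a replicate 2 peak by at least 1 bp. Of the 1190 replicate 2 peaks, 877 (73.7%, 71.1 to 76.2%) overlapped a replicate 1 peak. Circular shifts of the peaks along their chromosomes gave a mean overlap of 1.28% and 1.34% (two-sided permutation p = 0.0001 for each, the smallest that 10000 shifts can give). Over the 866 pairs of shared peaks, −log10 q in replicate 1 and replicate 2 gave Spearman's rho of 0.797 and Pearson's r of 0.886 on log values. The permutation p was 1e-05 for both, the smallest that 100000 permutations can give, and r was 0.881 without the 2 farthest pairs. These are correlations across peaks, which are not independent replicates. The median log2 ratio of replicate 1 to replicate 2 heights was 0.01, with an SD of 0.48 over the pairs.

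Peaks found in both replicates were higher and wider than those found in only 1. In replicate 1, median −log10 q was 6.67 for the 871 shared peaks and 3.64 for the 376 others, and median width was 430 against 328 bp. In replicate 2, median −log10 q was 6.68 for the 877 shared peaks and 3.61 for the 313 others, and median width was 422 against 315 bp. Each of the 4 differences had a two-sided permutation p of 1e-05, raw and after Benjamini-Hochberg adjustment. That is the smallest that 100000 permutations can give. These differences are partly built in. Every list holds only peaks below a q cut-off, and a peak near it is more easily missed in the other list. A wider peak also meets the 1 bp overlap rule more readily. With a reciprocal overlap of 50%, the width differences were 70 bp in replicate 1 and 80 bp in replicate 2. How much the cut-off alone would give was not tested. The labels do not say that the replicates were separate cultures. The p-values here measure only variation across the peaks of these lists, not between samples. Differences between the 2 replicates may be technical, and intervals cover counting error only.

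**Figure D2:**
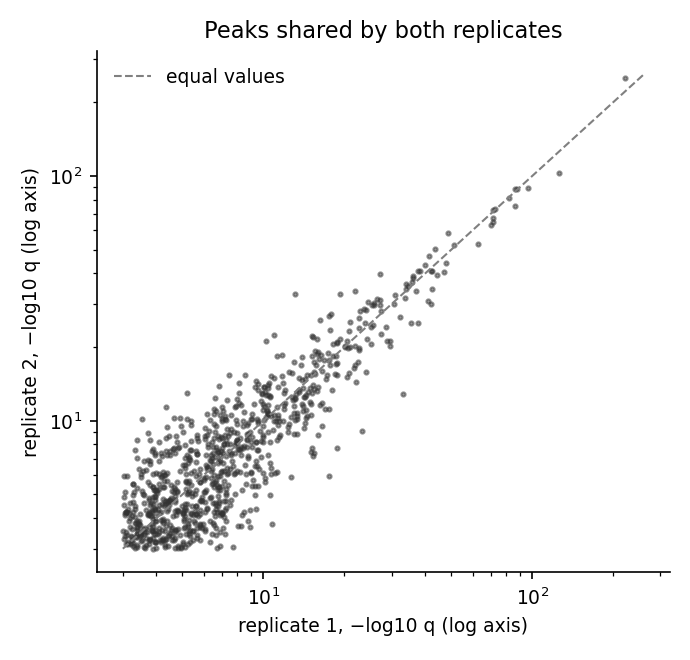
Height of each of the 866 shared peak pairs, as −log10 q in replicate 1 (x, log axis) and replicate 2 (y, log axis). Each point is 1 pair, the dashed line marks equal values, and Spearman's rho was 0.797.

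The series list took in nearly all replicate peaks and added weaker ones. Of the replicate 1 peaks, 1215 (97.4%) overlapped a series peak, and of the replicate 2 peaks, 1154 (96.97%) did. In the other direction, 854 series peaks (28.4%) were found in both replicates, 351 (11.7%) in replicate 1 only, 282 (9.38%) in replicate 2 only and 1519 (50.5%) in neither. Median −log10 q was 14.2 for the series peaks found in both and 3.82 for those found in neither. All of the 100 highest series peaks were found in both replicates, as were 97% of peaks 101 to 500 and 61.4% of peaks 501 to 1000. The share fell to 5.7% for peaks 1001 to 2000 and 0.199% for peaks 2001 to 3006.

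The highest peak of both replicate lists had no counterpart in the series list. It lay near the right end of chromosome I, at 15064003 to 15067643 in replicate 1 (3641 bp, q = 2.863e-222) and at 15064015 to 15067640 in replicate 2 (3626 bp, q = 2.046e-251). This peak was singled out after its values were seen. The next highest replicate peak without a series peak, near 931227 on III, ranked 286 in replicate 1 and 223 in replicate 2. Series ranks 1 to 10 were all present, and the lowest rank number that the series list lacked was 1897. Of 13 other replicate peaks in the last 500 kb of I, 0 lacked a series peak.

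Peaks were then counted per chromosome and set against chromosome length, a comparison that was planned for X and extended to all 6 chromosomes after the data were seen. Chromosome III carried 584 series peaks (19.4%, exact 95% interval 18.03 to 20.9%) on 13.8% of the length (exact binomial test, adjusted p = 2.747e-17). Chromosome IV carried 293 peaks (9.75%, 8.71 to 10.9%) on 17.4% of the length (exact test, adjusted p = 1.217e-31). Chromosome I held 17.2% of the peaks on 15.1% of the length (exact test, adjusted p = 0.00285). By the same exact test, the shares of II (15.04%, adjusted p = 0.761) and V (20.4%, adjusted p = 0.672) did not differ detectably from their shares of length. X carried 547 peaks (18.2%, 16.8 to 19.6%) on 17.7% of the length, which was not a detectable difference (exact binomial p = 0.444, adjusted p = 0.666). All adjusted values are Benjamini-Hochberg over 6 two-sided exact binomial tests. The 6 tests are not independent, because shares within a list depend on each other. The low share on IV raises those of the other chromosomes, so their results, with or without a detectable difference, rest partly on it. No test was made with IV set aside.

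The excess on I was not detectable in either replicate list, at 16.4% in replicate 1 (adjusted p = 0.214) and 15.6% in replicate 2 (adjusted p = 0.747, exact tests). The replicate lists gave mean shares of 21.1 ± 0.525% on III, 5.86 ± 0.212% on IV and 20.7 ± 1.61% on X (SD, n = 2). The share on X was 21.9% in replicate 2 (adjusted p = 0.000447 over 6 exact tests) and 19.6% in replicate 1 (adjusted p = 0.132), and 20.3% among series peaks found in both (exact p = 0.0484); the lists were not tested against each other. Windows of 500 kb allow for peaks lying close together, but not for density that varies over longer stretches, since neighbouring windows were treated as independent. They gave 21.2 ± 6.85 series peaks per window on III against 13.96 ± 6.89 elsewhere (SD, n = 27 and 170 windows). On IV they gave 8.5 ± 3.91 against 16.3 ± 7.14 (SD, n = 34 and 163). The permutation p was 1e-05 for both chromosomes, the smallest that 100000 permutations can give, and 0.769 for X. For X the window permutation p was 0.305 in replicate 1 and 0.0219 in replicate 2 (7.34 peaks per window against 5.66 elsewhere). The windows elsewhere include those of IV, which had a mean of 1.94 peaks in replicate 2 and so lower that value. Likewise, the low share on IV raises the share on X in each list, and X was not tested with IV set aside.

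Chromosome IV also differed from the rest in how its peaks carried over from the series list to the replicate lists. Over peaks found in all 3 lists, the series −log10 q divided by the sum of the replicate values had a median of 1.48 for the 55 peaks on IV and 1.03 for the 799 elsewhere (difference 0.444, permutation p = 1e-05, the smallest possible). Chromosome I stood next, at 1.15, and the other 4 lay between 0.995 and 1.04. Of series peaks 1 to 500, 85.96% on IV and 99.1% elsewhere were found in both replicates (Fisher's exact test, adjusted p = 1.23e-05), and 100% of either were found in at least 1. Of series peaks 501 to 1000, 6 of 56 on IV (10.7%) and 301 of 444 elsewhere (67.8%) were found in both replicates (Fisher's exact test, adjusted p = 2.3e-16 over 8 tests), and 53.6% and 97.1% in at least 1 (exact adjusted p = 4.95e-18). Of peaks 1001 to 2000, 0 of 99 on IV and 6.33% elsewhere were found in both (exact adjusted p = 0.00736), and 1.01% and 51.7% in at least 1 (exact adjusted p = 7.38e-27). Of peaks 2001 to 3006, few were found in both anywhere (0 of 81 on IV and 0.216% elsewhere, exact adjusted p = 1), and 0 and 6.38% were found in at least 1 (exact adjusted p = 0.0152). Both measures were chosen after the data were seen, and they are not independent of each other. Each depends on how replicate heights compare with series heights.

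**Figure D3:**
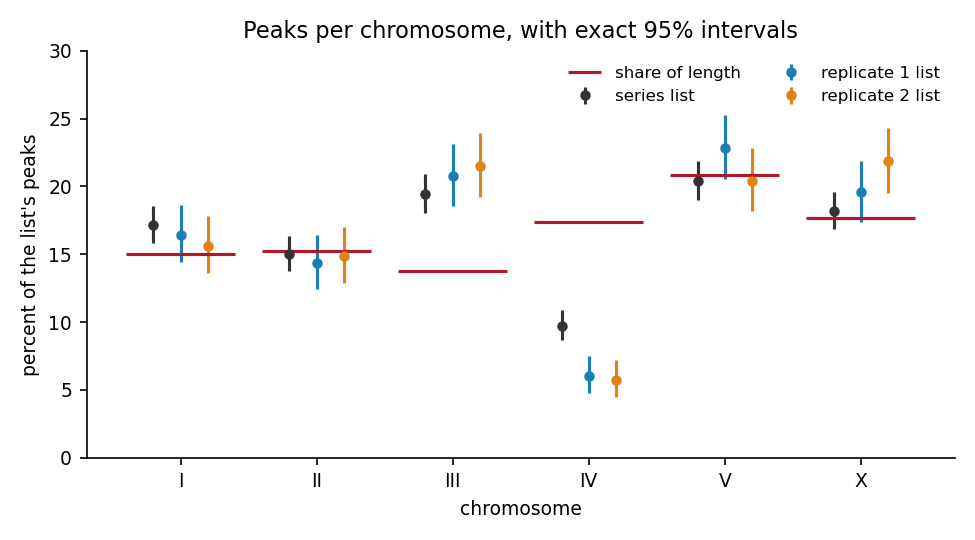
Percent of each list's peaks (y axis) on each chromosome (x axis) for the series list and the 2 replicate lists, with exact 95% binomial intervals as bars and the chromosome's share of length as a red line. IV lies below its line and III above it in all 3 lists.

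The highest peaks were concentrated on X. It held 9 of the 10 highest series peaks, 16 of the 25 highest, 26 of the 50 highest (52%, exact 95% interval 37.4 to 66.3%) and 35 of the 100 highest (35%, 25.7 to 45.2%). Against X's share of length, the share among the 50 highest had a two-sided exact binomial adjusted p of 2.99e-07. The corresponding counts among the 50 highest were 23 in replicate 1 and 24 in replicate 2. Below the 100 highest peaks, X held 16.5% of peaks 101 to 500, 16% of peaks 501 to 1000, 17.5% of peaks 1001 to 2000 and 18.99% of peaks 2001 to 3006. The median −log10 q was 5.36 on X and 5.37 on autosomes (permutation p = 0.979), whereas the 95th percentile was 48.7 on X and 27.3 on autosomes. The series peaks on X were not detectably wider than autosomal ones (median 405 against 389 bp, permutation p = 0.154), but those of replicate 1 were (456 against 391 bp, p = 3e-05), as were those of replicate 2 (436.5 against 385 bp, p = 0.00134). The numbers of highest peaks counted here were chosen after the data were seen, and the adjusted p is over all 16 counts made.

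**Figure D4:**
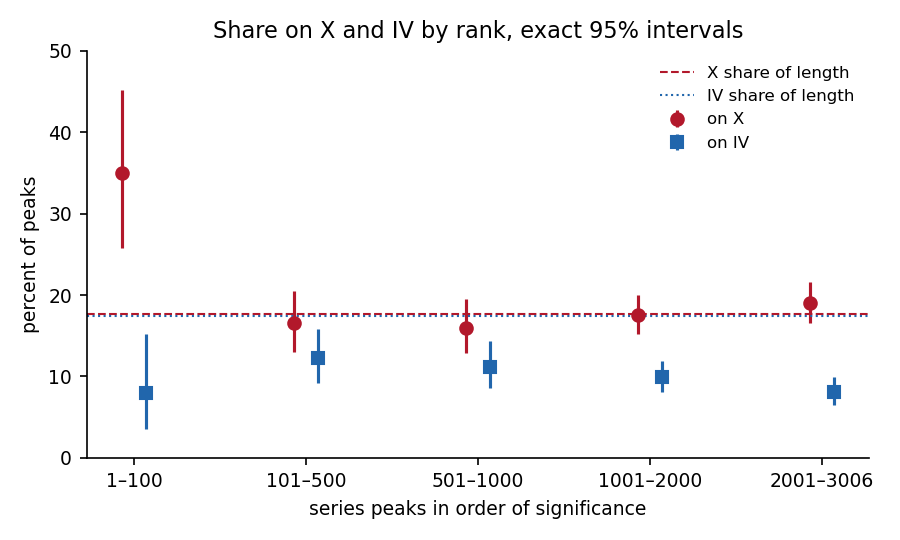
Percent of series peaks (y axis) on X (circles) and IV (squares) in 5 ranges of rank (x axis), with exact 95% binomial intervals as bars and each chromosome's share of length as a horizontal line. X holds 35% of the 100 highest peaks and 16 to 19% of the later ranges.

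The position of peaks within chromosomes was compared because the centres of C. elegans autosomes are rich in genes and recombine less than the arms. On autosomes, 1012 of 2459 series peaks (41.2%, exact 95% interval 39.2 to 43.1%) lay in the central 33.3% of the chromosome. Circular shifts gave a mean of 33.4% and a central 95% range of 27.7 to 39.1% (two-sided permutation p = 0.0039, 10000 shifts). By chromosome the central share was 43.02% on I, 44.03% on II, 38.2% on III, 33.4% on IV and 43.97% on V. On X it was 25.8% (permutation p = 0.135), and 46.2% of X peaks lay in the rightmost 33.3% (permutation p = 0.0002). The difference between autosomes and X in the central share was 15.4 percentage points (p = 0.0057), and it was 13.8 (p = 0.0076) in replicate 1 and 15.5 (p = 0.0054) in replicate 2, by the same permutation of shifts. The comparison with X was added after the data were seen.

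A cluster of unusually wide peaks stood out on chromosome IV. Peaks wider than 3 kb numbered 14 in the series list and 7 in each replicate list, and 3 of them in every list lay side by side on IV. In the series list these spanned 9048087 to 9057102 (9016 bp, −log10 q 46.9), 9062407 to 9066128 (3722 bp, 27.5) and 9067399 to 9078971 (11573 bp, 48.99). Together they covered 24311 of 30885 bp, or 78.7%. They made up 14.1% of all peak length on IV in the series list, 39.8% in replicate 1 and 39.5% in replicate 2. In a gene table of assembly WBcel235, whose coordinates were not used, nhr-11 (CELE_ZC410.1) is on IV and unc-119 (CELE_M142.1) on III. Whether the wide peaks cover nhr-11 was not analysed here. This region was singled out after its values were seen.

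**Figure D5:**
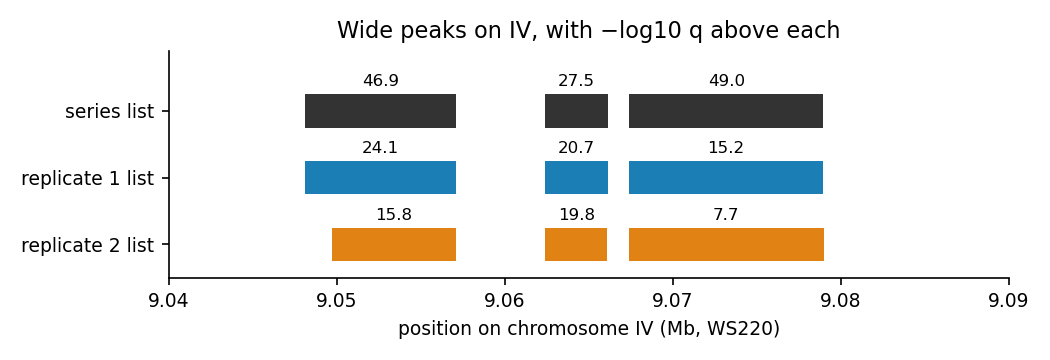
Map of the wide peaks on IV, with position in Mb (WS220) on the x axis and 1 row per list, where each bar is a peak drawn to scale and the number above it is its −log10 q. Every list has 3 wide peaks at nearly the same positions, and the widest of the series list is 11573 bp.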

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

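Alternatives for the shares on III and IV and for the 50 highest peaks, and those with merged peaks, 500 kb windows, protein-coding genes or without the wide peaks on IV, were chosen after the data were seen. Of 51 alternatives, 47 kept the direction and the side of the 0.05 threshold, and 4 moved the share of peaks on X past it. All 4 concern that single planned result, so the count of 47 does not show that it is stable. The share on X kept its side of 0.05 with the lower-q part of the list, replicate 1 alone, no wide peaks on IV, merged peaks and 500 kb windows. That share was 18.2% against 17.7% of length (exact p = 0.444). It was 20.3% among peaks found in both replicates (exact p = 0.0484), and it ranged from 19.6% (p = 0.0809) to 21.9% (p = 0.000223) over the replicate lists taken alone. The same 18.2% exceeded X's share of all annotated genes, 12.8% (p = 7.19e-17), and of protein-coding genes, 13.7% (p = 3.81e-12), by exact binomial tests. These differ by construction in what X is compared with, and the cause of the difference between lists was not tested. Shares within a list depend on each other, so a lower share on IV raises the rest. IV held 9.75% of the series list and 6.44% of series peaks found in both replicates. It held 6.01% of the replicate 1 list and 5.71% of the replicate 2 list. The share on X was not tested with IV set aside. In the gene table, IV holds 42.02% of all annotated genes but 16.4% of protein-coding genes, which lowers the all-gene shares of the other chromosomes. The all-gene alternative for IV therefore says little. Replicate overlap ranged from 53.7% (centres within 100 bp) to 76.4% (lower-q part of each list) of replicate 1 peaks. The central share of autosomal peaks ranged from 40.3 to 42.04% with the centre as planned, and was 59.2% for the central 50% of length. X among the 50 highest peaks ranged from 23 to 26. No alternatives were run for the analyses of gene 5′ ends, gene lists, sequence motifs and transgene loci, which were themselves not run. No paired analysis was possible because the input libraries had no values here, so ChIP and input of the same number could not be compared. Depth is unknown, so how far it limits the weak peaks cannot be stated.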

Other observations

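Tests chosen only after the result was seen were those of peak width on X, of a common lower scaling on IV and of series against replicate heights on IV, and peak spacing was also examined after the data were seen. The rank numbers missing from the series list, the replicate peaks near the end of I, and series against summed replicate heights were examined by criteria written beforehand and are given as values only. Peaks lay closer together than random placement gives. Of 3000 gaps between neighbouring series peaks, 17.3% were 2 kb or shorter, against 6.16% for peaks placed at random (one-sided permutation p = 0.000999, the smallest that 1000 draws can give). The shares were 10.4% against 2.73% in replicate 1 and 11.99% against 2.64% in replicate 2, with the same p. Joining peaks within 2 kb left 2486 series, 1118 replicate 1 and 1048 replicate 2 sites. Over the 854 series peaks found in both replicates, the series −log10 q was 1.03 times the sum of the replicate values at the median (interquartile range 0.974 to 1.13) and exceeded both replicate values in 99.4%.

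The highest peaks were concentrated on X, and 3 technical explanations were tested. A common scaling of significance on X would need a factor of 2.07 to give the 23 X peaks above −log10 q of 60. It would then predict 528 X peaks above 6.21, and 232 were found (exact 95% Poisson interval 203 to 264), which argues against it. That prediction takes in every autosomal peak, because 6.21 is the q cut-off after scaling. The result is therefore not independent of the like peak density and median height of X and autosomes given above. A few neighbouring sites are argued against for the 50 highest X peaks, which lay in 25 windows of 500 kb. Random draws of X peaks had a mean of 26.4 windows and a 2.5th percentile of 23. The excess on X lay in the 100 highest series peaks, of which 35 were on X, so these 50 reach beyond it. Clustering among the 35 alone was not tested. Wider calls on X are argued against as the whole cause in the series list by width-matched peaks. Of its 100 widest X peaks, 67% (exact 95% interval 56.9 to 76.1%) were higher than the median autosomal peak of like width. No width matching was done in the replicate lists, where X peaks were wider at the median, so the explanation was not tested there. Differences in mappability, base composition or input coverage on X stay open, because they need reads or a genome. No biological explanation was tested, and a set of particularly strong NHR-11 sites on X remains a possible explanation.

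Chromosome IV carried 293 series peaks where the density of peaks on the other chromosomes predicts 572. Loss of calls only near the threshold is argued against, since IV held 10.6% of the lower-q part of the list (upper 95% limit 12.2%) against 17.4% of length. A common lower scaling on IV could account for the heights: a factor of 0.572 predicts 9.91 peaks above −log10 q of 30, and 14 were found (exact 95% Poisson interval 7.65 to 23.5). An equal loss at all heights predicts 13.4 and is not separated from scaling by this count, while no loss, at the density of the other chromosomes, predicts 26.1. Whether lower significance in the replicate lists lies behind IV's still lower share there is not decided by the ratio of series height to summed replicate height, 1.48 on IV and 1.03 elsewhere, because that ratio restates the poor recovery of IV peaks that had already been seen. How the caller scaled ChIP to input on each chromosome stays open, and no biological explanation was tested.

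For the 3 wide peaks on IV, extra copies of the nhr-11 locus carried by the transgene are a candidate explanation, since copies raise coverage over a long stretch. Copies would raise input coverage as well, so this explanation needs an incomplete correction for input. How the input entered the calling is not given. The test compared −log10 q per kb, which was at most 7.38 in the 3 peaks, all found in both replicates, against a 5th percentile of 16.3 and a median of 45.7 among 271 other series peaks above 20. The values met the criterion written beforehand for this explanation, but the test was judged void after its result was seen, because the peaks had been picked for their width, which itself lowers height per kb. The 11 other series peaks wider than 3 kb ran from 0.882 to 27.6, with a median of 16.3. Among them, only those beginning at II 10370734 (0.882, −log10 q 3) and II 10444977 (5.72, −log10 q 18.6) lay below 7.38. The 3 thus lay at the low end of wide peaks. Those of 9016 and 11573 bp were, however, wider than any of the 11, which reached 5404 bp. Height per kb therefore does not settle the question. Extra copies and broad binding cannot be told apart without input coverage and a WS220 annotation, and no biological explanation was tested.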
